A study of Acropora tenuis
Cladocopium goreaui with 23 samples.

How the data were processed

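Coral larvae of Acropora tenuis that held the dinoflagellate alga Cladocopium goreaui were sequenced as whole symbioses, so that each of the 23 libraries holds RNA of the animal and of its alga. Per the labels' protocols, RNA was extracted with a Zymo Quick-RNA MiniPrep kit, and Illumina TruSeq Stranded mRNA v2 libraries were read as paired 100 bp reads on a NovaSeq 6000. FastQC, STAR 2.5.3 and limma 3.36.5 are listed in the submitters' processing notes, without roles. The genome builds, the annotation and the counting tool are not given in the sources used here.

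The authors deposited 2 tables of raw counts, 1 for the host and 1 for the symbiont, per the file headers with 1 row per exon and 1 column per library. There were 216537 exons of 30327 genes for the host, and 360656 exons of 35913 genes for the symbiont. No row lacked a gene and 0 columns belonged to no sample. The column headers write the wild-type strain as WT10 and the sample labels write it as WT1. Columns were matched through the library numbers that both carry. Exon counts were summed to gene counts, a choice made once the tables had been read. How a read over 2 exons was counted is not stated, so a gene with many exons may count such reads more than once. Genes that share reads with near-identical copies are uncertain for the same reason, because the treatment of such reads is not stated.

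Totals ranged from 6454880 to 25670169 counts per library for the host and from 3628085 to 6975699 for the symbiont. The low-count filter of edgeR, set by strain, left 18996 host genes with 99.9% of the host counts and 18192 symbiont genes with 99.7% of the symbiont counts. Counts of each organism were scaled by TMM factors (host 0.938 to 1.09, symbiont 0.942 to 1.08) and tested with edgeR 4.0.16 in R 4.3.3, by the robust quasi-likelihood F-test with strain as the only factor and all 23 libraries in 1 fit. Genes with a Benjamini-Hochberg adjusted p under 0.05 passed the threshold. The mean of the 3 heat-selected strains, with equal weight per strain, and each heat-selected strain were compared with WT1, and the 3 heat-selected strains with each other. Levels are CPM, as edgeR computes them on TMM-scaled library sizes, given as mean ± SD over libraries. A standard error (SE) of a log2 fold change was taken as its size over the square root of F.

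The symbiont share of a library is its symbiont count total as a percent of both totals. Differences of mean shares were tested with exact two-sided permutation tests over all regroupings, with Benjamini-Hochberg adjustment over 6 comparisons. A fold against a strain without a single count was computed against a floor of 3 counts over that strain and written as a lower bound. With 1 to 3 counts, the ratio is given with its exact 95% interval. Such intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

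The design has 1 wild-type strain, so a difference from WT1 is a difference between strains. Libraries of a strain are not replicates of the selection. The labels do not say whether libraries of a strain came from separate larval cultures, and p-values then measure only the spread between these libraries, which may be technical. Every pair of libraries within a strain differed by more than independent counts would. Reads counted on more than 1 exon would also raise this value, so it does not measure biological spread. The lowest chi-square per degree of freedom, over genes with at least 10 counts in the pair, was 1.46 for the symbiont and 8.43 for the host.

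Genes named in the text had to pass the threshold, have library values that did not overlap between the compared strains, and reach 5 CPM in the higher strain. The files do not pair gene IDs with names, so at most 2 IDs that rose and 2 that fell, those with the largest changes under this rule, are named per comparison. The 16 symbiont and 21 host gene lists fixed beforehand could not be matched and were not tested. Gene positions are not given either. A test on genes with consecutive ID numbers was added after the data had been seen.

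The test was checked on counts simulated from the real means, spreads and library sizes, with 200 genes changed. For SS3 vs WT1, 52.2% of symbiont genes changed 1.5-fold, 77.6% of those changed 2-fold and 98.5% of those changed 4-fold were recovered among 18192 genes, and 3.80% of calls were false. For SS8 vs WT1 in the host, 49.3%, 61.2% and 89.4% were recovered among 18996 genes, and 8.28% of calls were false. The simulated genes were drawn independently, without influences shared by many genes of a library, so the share of false calls in the real data may differ. Overlaps of the comparisons that share the WT1 libraries were set beside 20 simulations of unchanged groups and beside 10 splits of WT1 into groups of 3 libraries. In the simulations all libraries, WT1 included, were drawn from the WT1 means. Influences particular to the real WT1 libraries are thus absent from them.

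The results were recomputed with RLE size factors, with library totals only, without the filter, with at least 50 counts in 5 libraries, with DESeq2 1.42.0, with limma-voom (limma 3.58.1), with only the compared strains, with the replicate number as a block, with a 2-fold minimum, and without each library in turn. These alternatives were fixed before the data were examined. Fits to the most abundant exon of each gene, with the symbiont share as a covariate (host), and with the other organism's TMM factor as a covariate were added later. SciPy 1.17.1 gave the exact tests and Matplotlib 3.10.9 the plots.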

Results

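The deposited counts described coral larvae (Acropora tenuis) that lived with 1 of 4 strains of the photosynthetic alga Cladocopium goreaui, a dinoflagellate symbiont of reef corals. Strains SS3, SS5 and SS8 had been selected under heat, and WT1 was the wild-type strain. All libraries came from symbioses kept at 27 °C. There were 6 libraries each with SS3, SS5 and WT1, and 5 with SS8. The series title names coral bleaching tolerance as its subject. The comparisons therefore asked how gene expression in hospite differed between heat-selected and wild-type symbionts, and how the host differed with them.

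Host totals ranged from 17677920 to 22920005 counts with SS3, from 17200441 to 24153079 with SS5, from 6454880 to 18781786 with SS8 and from 18441056 to 25670169 with WT1. Symbiont totals ranged from 3682727 to 5680299 counts with SS3, from 3778866 to 4656359 with SS5, from 3628085 to 6975699 with SS8 and from 4120567 to 5759510 with WT1. The shallowest library was SS8 replicate 5, with 6454880 host and 3628085 symbiont counts.

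The alga took a larger share of the counts in larvae with SS8. Its share was 29.98% ± 4.31 with SS8 (SD, n = 5), against 18.7% ± 3.64 with WT1, 18.9% ± 1.88 with SS3 and 16.5% ± 1.97 with SS5 (SD, n = 6 each). SS8 lay above each of the other strains without overlap of libraries, by 11.3 percentage points over WT1, 11.1 over SS3 and 13.5 over SS5. Each of these had an exact permutation p of 0.00433, the smallest that this design allows, and an adjusted p of 0.00866. SS3 and WT1 differed by 0.164 points (exact permutation p = 0.918, adjusted p = 0.918), SS5 and WT1 by -2.22 points (exact p = 0.216, adjusted p = 0.260) and SS5 and SS3 by -2.38 points (exact p = 0.0649, adjusted p = 0.0974). The last difference passed the threshold without SS5 replicate 5 (-3.07 points, exact permutation adjusted p = 0.0195), and its adjusted p ranged from 0.0195 to 0.3 over 16 alternatives. A share of counts measures RNA and not numbers of algal cells.

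**Figure D1:**
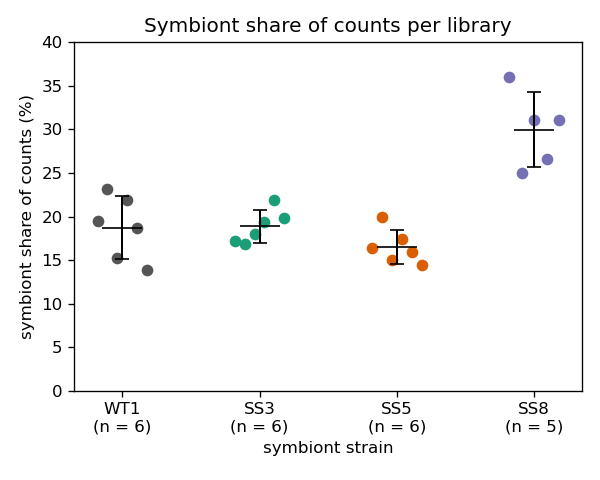
Symbiont share of counts (%) per library, by symbiont strain. Points are libraries, and bars are means ± SD. The 5 SS8 libraries lie between 25.0% and 36.0%, above the libraries of the other strains (13.8% to 23.2%).

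The first principal component of symbiont log2 CPM (24.2% of the variance) parted the 6 WT1 libraries, at 34.9 to 41.4, from the libraries of the heat-selected strains, at -32.3 to 2.97. For the host, the first component (29.1%) ran from WT1 (-69.9 to -40.8) over SS3 (-23.9 to 1.22) to SS8 (30.3 to 52.2). The SS5 libraries lay between 15.2 and 44.4 except replicate 6, which lay at -6.97 among those with SS3.

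**Figure D2:**
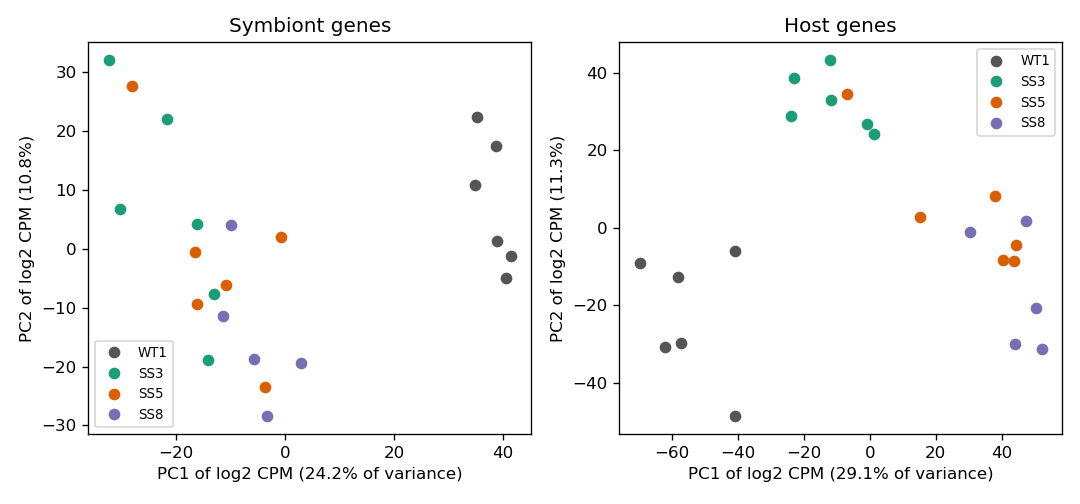
First 2 principal components of log2 CPM for symbiont genes (left) and host genes (right), with the percent of variance on each axis. Points are libraries, coloured by symbiont strain. The WT1 libraries stand apart on the first component in both organisms.

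In the symbiont, the mean of the heat-selected strains differed from WT1 in 2857 of 18192 genes. 1164 were higher and 1693 lower in the heat-selected strains, and most differences were small, since 304 reached 2-fold (116 higher, 188 lower). The 2-fold counts depended on the filter. They were 153 higher and 391 lower without it, and 74 and 59 with at least 50 counts in 5 libraries. A few genes were close to absent on 1 side. SymbC1.scaffold1914.2.m1 had 0 counts in the 6 WT1 libraries and 25.92 ± 5.85 CPM in SS3 (SD, n = 6), 230.0 ± 26.4 in SS5 (SD, n = 6) and 93.4 ± 21.5 in SS8 (SD, n = 5), at least 255-, 2264- and 920-fold higher. SymbC1.scaffold1914.4.m1, on the same scaffold by its ID, also had 0 counts in WT1 and reached 4.21 ± 1.90, 50.0 ± 5.80 and 32.9 ± 10.51 CPM in SS3, SS5 and SS8, at least 41.5-, 493- and 324-fold higher. SymbC1.scaffold15080.1.m1 showed the opposite pattern, with 19.9 ± 3.16 CPM in WT1 (SD, n = 6), 2 counts over the SS3 libraries (ratio 285, exact 95% interval 78.6 to 2361) and 0 counts in SS5 and SS8, at least 166- and 199-fold lower. SymbC1.scaffold5068.1.m1 fell from 67.6 ± 3.45 CPM in WT1 to 0.143 ± 0.176 in SS3, 0.126 ± 0.215 in SS5 and 0.177 ± 0.119 in SS8. Adjusted p-values of these 4 genes, from edgeR's quasi-likelihood test, were 2.94e-12, 4.09e-10, 3.5e-25 and 2.31e-38.

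**Figure D3:**
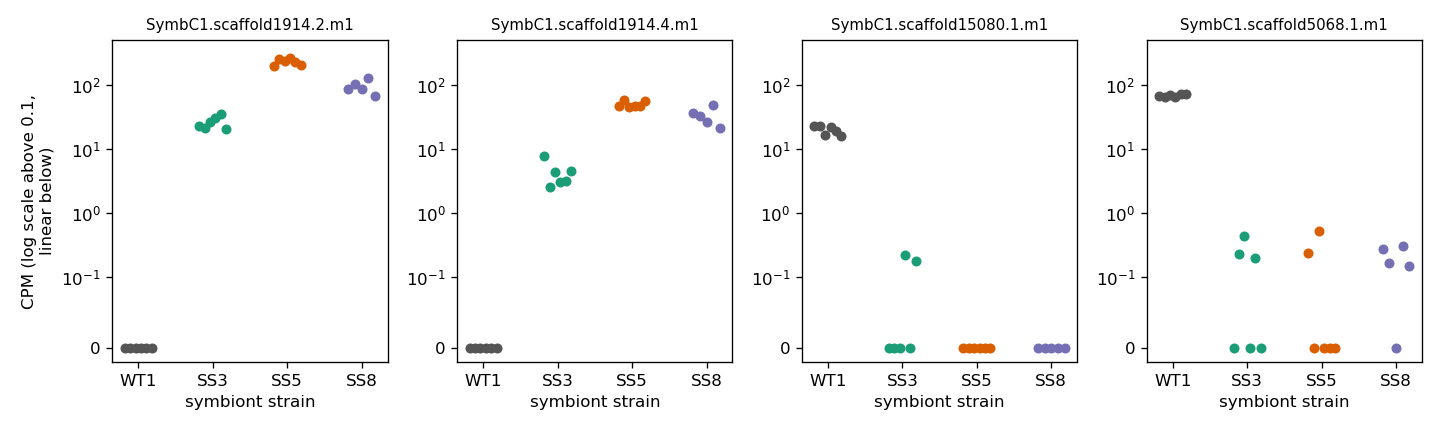
CPM of 4 symbiont genes per library, by symbiont strain (log scale above 0.1, linear below). Points are libraries. The first 2 genes have 0 counts in each WT1 library and are present in each heat-selected library. The other 2 are present in each WT1 library and near or at 0 elsewhere.

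Taken strain by strain, SS3 differed from WT1 in 3063 symbiont genes (1224 higher, 1839 lower), SS5 in 1754 (796 higher, 958 lower) and SS8 in 1736 (748 higher, 988 lower). SymbC1.scaffold1474.1.m1, with 1 count over the WT1 libraries, had 10.1 ± 6.74 CPM in SS3 (SD, n = 6), a ratio of 284 (exact 95% interval 50.48 to 11243). SymbC1.scaffold10964.1.m1 fell from 98.2 ± 22.9 CPM in WT1 to 1 count over the SS3 libraries, a ratio of 2812 (exact 95% interval 504 to 111098). SymbC1.scaffold2058.6.m1, at 25.3 ± 5.58 CPM in WT1, had 0 counts in SS3, at least 239-fold lower. SymbC1.scaffold4895.4.m1 rose in SS5 to 145 ± 17.1 CPM from 1 count over WT1 (ratio 4286, exact 95% interval 769 to 169325). SymbC1.scaffold5068.2.m1, at 11.1 ± 2.73 CPM in WT1, had 0 counts in SS8, at least 111-fold lower. With the host's TMM factor of each library as a covariate, a setting chosen after the data were seen, 3169 genes passed for SS5, with 1741 higher and 1428 lower, so that the larger side changed.

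In all 3 comparisons with WT1, 770 symbiont genes passed in the same direction, 346 higher and 424 lower. Simulated unchanged strains, set against simulated WT1 libraries that they shared, gave 0 such genes in each of 20 simulations. These simulations leave out real differences and show only chance without them. Independent lists of these sizes would share 7.46. With WT1 split into groups of 3 libraries so that 2 strains met different ones, SS3 and SS5 shared 608 genes on average, SS3 and SS8 shared 705 and SS5 and SS8 shared 504, against 752, 847 and 610 where both strains met the same 3 libraries and 61.0, 66.6 and 37.0 for independent lists, so that part of each overlap comes with the shared libraries. 61 genes passed in opposite directions in some pair of the comparisons. The 770 genes set WT1 apart from every other strain in 1 direction, whereas 96 genes did so for SS3, 167 for SS5 and 72 for SS8. With the host's TMM factor as a covariate the 770 became 1268.

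Heat-selected symbionts differed less from each other. SS8 and SS3 differed in 348 genes (232 higher and 116 lower in SS8), SS8 and SS5 in 725 (241 higher, 484 lower) and SS5 and SS3 in 711 (447 higher, 264 lower). SymbC1.scaffold6714.2.m1 was higher in SS8 (16.3 ± 8.77 CPM, n = 5) than in SS5 (0.276 ± 0.391, n = 6), with log2 fold change 5.73 ± 0.46 (SE) and adjusted p = 7.35e-11 by edgeR's quasi-likelihood test. SymbC1.scaffold7583.2.m1 was highest in SS3, at 255 ± 18.7 CPM (SD, n = 6), against 67.1 ± 14.61 in SS8 (log2 fold change -1.93 ± 0.12 SE, adjusted p = 1.06e-11, edgeR) and 8.16 ± 1.96 in SS5 (-4.97 ± 0.15, adjusted p = 2.22e-19, edgeR). SymbC1.scaffold745.5.m1 was nearly private to SS5, with 31.6 ± 4.57 CPM there (SD, n = 6), 0 counts in SS3, 2 in SS8 and 14 in WT1. SymbC1.scaffold4366.3.m1 reached 149 ± 20.2 CPM in SS5 against 0.474 ± 0.507 in SS3 and 1.57 ± 0.442 in SS8. With the host's TMM factor as a covariate these 3 counts were 741 (380 higher, 361 lower), 1527 (464 higher, 1063 lower) and 1431 (884 higher, 547 lower).

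In the host, the mean of the heat-selected strains differed from WT1 in 5683 of 18996 genes, 2751 higher and 2932 lower. Large differences went mostly 1 way, with 1010 genes at least 2-fold higher and 177 at least 2-fold lower, and 418 against 16 at 4-fold. aten_0.1.m1.6676.m1 rose from 0.0779 ± 0.107 CPM with WT1 (SD, n = 6) to 23.1 ± 21.4 with SS3, 23.1 ± 7.23 with SS5 and 23.69 ± 25.498 with SS8 (log2 fold change 8.23 ± 1.02 SE, adjusted p = 2.59e-06, edgeR). aten_0.1.m1.25616.m1 rose from 0.206 ± 0.184 CPM to 27.4 ± 37.9, 81.7 ± 27.2 and 49.5 ± 29.8 (7.87 ± 0.92, adjusted p = 1.22e-06, edgeR). Single libraries weighed on these levels: the mean of aten_0.1.m1.25616.m1 with SS3 was 12.1 CPM without SS3 replicate 6, and that of aten_0.1.m1.6676.m1 was 15.2 with SS3 without replicate 5 and 12.8 with SS8 without replicate 7. aten_0.1.m1.4424.m1 fell from 17.01 ± 3.47 CPM to 6.17 ± 1.82, 1.88 ± 0.410 and 2.10 ± 0.963 (-2.56 ± 0.18, adjusted p = 6.06e-10, edgeR). aten_0.1.m1.4422.m1 fell from 23.01 ± 4.79 CPM to 9.68 ± 2.23, 4.14 ± 0.789 and 2.76 ± 0.946 (-2.26 ± 0.16, adjusted p = 4.96e-10, edgeR). Which side held more genes depended on the setting. With counts scaled by library totals alone 3268 genes were higher and 2160 lower, and the higher side was the larger in 5 of 10 alternative settings and without 1 library in 16 of 23 cases.

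The 418 host genes at least 4-fold higher had low levels, with a median of 0.407 CPM with WT1, 1.91 with SS3, 4.17 with SS5 and 4.92 with SS8. 348 of them were higher with SS3 than with WT1 on their own, 410 with SS5 and 410 with SS8. Their median log2 fold change was 2.13 with SS3 and 3.46 with SS8. These values describe genes picked by the mean comparison.

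**Figure D4:**
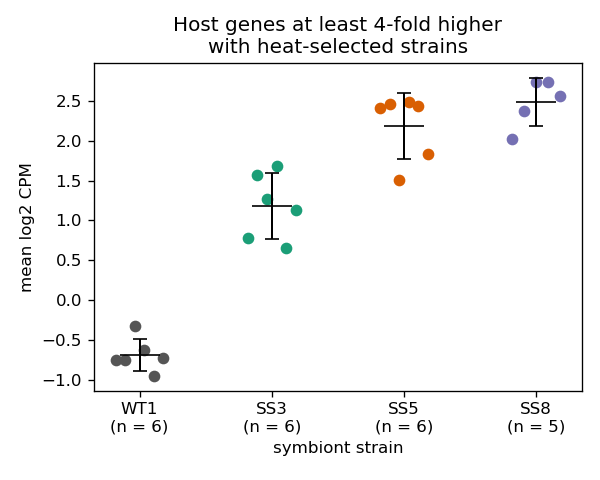
Mean log2 CPM per library of the 418 host genes at least 4-fold higher with heat-selected strains than with WT1, by symbiont strain. Points are libraries, and bars are means ± SD. Libraries with WT1 lie between -0.94 and -0.32, and those with SS3 between 0.65 and 1.68.

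Strain by strain, 5021 host genes differed between SS3 and WT1 (2335 higher, 2686 lower), 5041 between SS5 and WT1 (2564 higher, 2477 lower) and 6123 between SS8 and WT1 (3020 higher, 3103 lower). With library totals alone the higher side was the larger in each, with 2777 higher and 2179 lower for SS3, 3321 and 1506 for SS5, and 3287 and 2820 for SS8. For SS8 the larger side changed in 7 of 11 settings and without 1 library in 10 of 11 cases, for SS3 in 2 of 11 (1 of them a tie) and 5 of 12, and for SS5 in 2 of 11 and 0 of 12. aten_0.1.m1.15227.m1 was lower with SS3 (0.948 ± 0.349 CPM, n = 6) than with WT1 (13.7 ± 20.4, n = 6; log2 fold change -3.86 ± 0.70 SE, adjusted p = 0.000276, edgeR). The WT1 mean was 5.39 CPM without WT1 replicate 7, and the fold change, then -2.51, still passed the threshold. aten_0.1.m1.30450.m1 was also lower with SS3 (-3.06 ± 0.89, adjusted p = 0.0134, edgeR), but this rested on WT1 replicate 7, without which it was -1.04 ± 0.60 (adjusted p = 0.231, edgeR, within a range of 0.00103 to 0.231 over 23 alternatives). With all libraries kept, it also did not pass with limma-voom (-1.68, adjusted p = 0.17) or with the replicate block (-2.10 ± 1.06, adjusted p = 0.214, edgeR). aten_0.1.m1.10088.m1 was lower with SS5, at 0.913 ± 0.201 CPM against 6.63 ± 3.13. aten_0.1.m1.16887.m1 had 0 counts with WT1 and 5.92 ± 4.55 CPM with SS8 (n = 5), at least 249-fold higher (adjusted p = 0.00175, edgeR, and from 1.54e-08 to 0.0599 over 22 alternatives, the highest with the symbiont share as a covariate). Its log2 fold change was 9.90 ± 2.14 without that covariate and 9.67 ± 3.25 with it, so the call ended through a larger SE at a similar fold. With that covariate, chosen after the data were seen, 2717 genes differed between SS8 and WT1.

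Across all 3 comparisons with WT1, 1956 host genes passed in the same direction, 1041 higher and 915 lower. The simulations of unchanged groups, chance without real differences, gave 0, and independent lists would share 107. With split WT1 libraries, SS3 and SS5 shared 1524 genes on average, SS3 and SS8 shared 1475 and SS5 and SS8 shared 2108, against 1886, 1727 and 2475 where both met the same 3 libraries and 336, 453 and 465 for independent lists. 401 host genes passed in opposite directions in some pair of the comparisons. WT1 was set apart from every other strain by the 1956 host genes, SS8 by 1358, SS3 by 970 and SS5 by 233. With the symbiont share as a covariate, 1170 genes passed in all 3. With it 221 differed between SS8 and SS5, so SS8 could then be set apart by no more than that.

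Among larvae with heat-selected strains, SS8 and SS3 differed in 6112 host genes (3276 higher and 2836 lower with SS8), SS8 and SS5 in 2676 (1421 higher, 1255 lower) and SS5 and SS3 in 3162 (1684 higher, 1478 lower). aten_0.1.m1.9273.m1 was higher with SS8 (11.3 ± 9.21 CPM, n = 5) than with SS3 (0.278 ± 0.261, n = 6; log2 fold change 5.37 ± 0.75 SE, adjusted p = 1.21e-05, edgeR). aten_0.1.m1.12840.m1 was lower with SS8 (2.65 ± 1.63 CPM) than with SS3 (24.9 ± 3.34; -3.26 ± 0.39, adjusted p = 2.75e-06, edgeR). aten_0.1.m1.1222.m1 was lower with SS8 (6.67 ± 0.757 CPM) than with SS5 (48.8 ± 17.3; -2.88 ± 0.22, adjusted p = 9.25e-09, edgeR). aten_0.1.m1.9813.m1 was higher with SS5 (13.8 ± 5.04 CPM) than with SS3 (0.856 ± 0.758), and aten_0.1.m1.34491.m1 was lower (2.25 ± 0.842 against 18.1 ± 7.77 CPM). Library totals alone gave 1009 higher and 1815 lower for SS8 against SS5, and 2170 higher and 1169 lower for SS5 against SS3. For SS8 against SS5 the larger side changed in 2 of 11 settings and without 1 library in 1 of 11 cases. For SS5 against SS3 it changed in 1 of 11 (the replicate block, 801 higher and 865 lower) and 0 of 12. With the symbiont share as a covariate, 2426 genes differed between SS8 and SS3 and 221 between SS8 and SS5, and aten_0.1.m1.9273.m1 no longer passed in either comparison, at 2.67 ± 1.07 against SS3 and 0.43 ± 1.41 against SS5, from 5.37 ± 0.75 and 3.96 ± 0.67 (adjusted p = 0.103 and 0.923, edgeR, the highest of 22 alternatives each, whose lowest were 1.75e-12 and 2.55e-07).

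**Figure D5:**
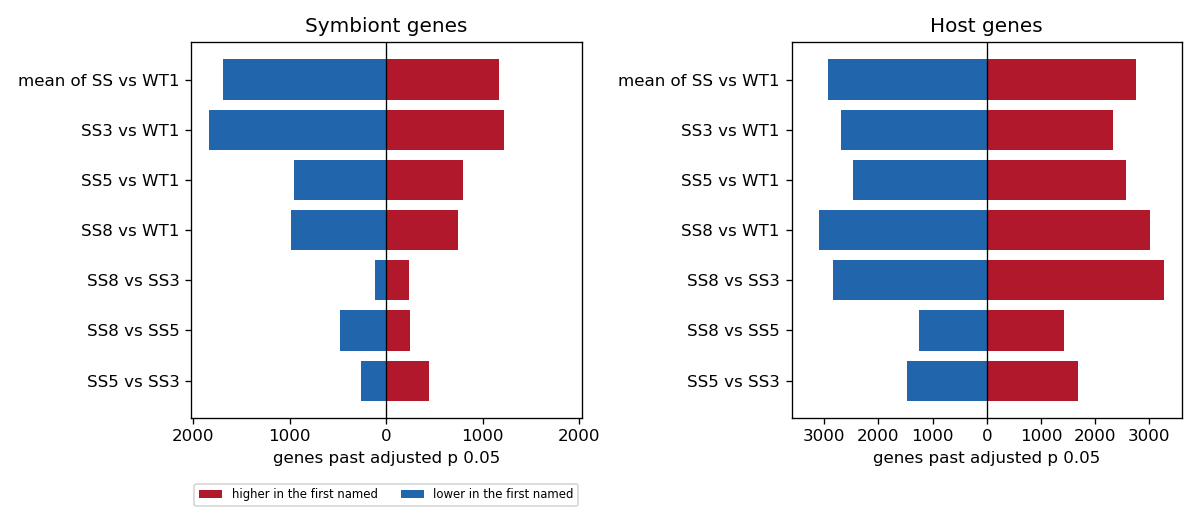
Genes past an adjusted p of 0.05 in each comparison, for the symbiont (left) and the host (right). Bars to the right count genes higher in the first named strain, and bars to the left genes lower in it ("mean of SS" is the mean of SS3, SS5 and SS8). In the symbiont the comparisons with WT1 count 1736 to 3063 genes and those among heat-selected strains 348 to 725.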

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

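The tests of depth and of the symbiont share on the library axis, the count of strain-private genes, the ratio over splits of WT1, the wild-type design and the count of genes with 1 or 2 exons were chosen after the result was seen. The other tests were chosen before their own results were seen, but the fit with the symbiont share as a covariate was added after the data had been examined.

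The symbiont total of SS8 replicate 5 stood apart from its strain, at 3.63 M counts (3628085) against a median of 6.73 M in the other 4. The SS8 share of symbiont counts exceeded the shares of SS3 and SS5 by 11.1 and 13.5 percentage points, so its difference from WT1 differed from theirs. Some genes changed in opposite directions against WT1 with 2 heat-selected strains and differed between them: 51 symbiont genes for SS3 and SS5, 12 for SS3 and SS8 and 30 for SS5 and SS8, and 49, 327 and 83 host genes for these pairs.

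Single libraries also stood apart in genes that met the naming rule. Of 133 sets of values tested, library totals and shares included, 21 had such a library, the symbiont total of SS8 among them. Chance gives about 1 in 20 only for normally distributed values. Some of these CPM values were near 0 and all lay on the high side, so no excess over chance follows. High symbiont values were SymbC1.scaffold1474.1.m1 in SS3 replicate 3 (23.5 CPM) and SS5 replicate 8 (20.99 CPM), SymbC1.scaffold2058.6.m1 in SS8 replicate 7 (0.581 CPM), and SymbC1.scaffold7937.3.m1 in SS3 replicate 4 (4.32 CPM) and SS5 replicate 1 (11.6 CPM). High host values were aten_0.1.m1.6676.m1 in SS8 replicate 7 (67.3 CPM) and WT1 replicate 1 (0.286 CPM), aten_0.1.m1.25616.m1 in SS3 replicate 6 (104 CPM), aten_0.1.m1.15227.m1 in SS3 replicate 7 (1.60 CPM) and WT1 replicate 7 (55.4 CPM), aten_0.1.m1.30450.m1 in WT1 replicate 7 (84.7 CPM), aten_0.1.m1.10088.m1 in SS3 replicate 6 (4.12 CPM) and aten_0.1.m1.16887.m1 in SS3 replicate 4 (1.12 CPM). Others were aten_0.1.m1.9273.m1 in SS3 replicate 7 (0.770 CPM) and SS5 replicate 7 (2.48 CPM), aten_0.1.m1.12840.m1 in SS5 replicate 6 (30.4 CPM), aten_0.1.m1.34884.m1 in SS3 replicate 6 (7.50 CPM) and WT1 replicate 6 (0.590 CPM), aten_0.1.m1.9813.m1 in SS8 replicate 7 (6.59 CPM) and aten_0.1.m1.25612.m1 in SS5 replicate 7 (71.1 CPM).

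Host genes at least 4-fold higher with the heat-selected strains were weighed against 3 technical explanations. Reads of another organism would pile up on few exons. 301 of the 418 genes, those with at least 3 exons, had a median of 75% of exons with at least 10 counts. Host genes matched on counts and exon number had 80%, a ratio of 0.938 (bootstrap 95% interval 0.875 to 1). The counts were summed over the heat-selected libraries and include host reads at the level seen with WT1 (median 0.407 CPM). Such host reads could cover the exons even if the rise fell on few of them, so the test cannot decide on the rise. The other 117 genes have 1 or 2 exons, too few for this test. Reads of another organism stay open for all 418 genes. With the symbiont share as a covariate, 98.8% of the 418 genes passed in the mean comparison. The median log2 rise with SS3 exceeded the change of the ratio of algal to host counts by 2.10, but 6 symbiont genes were silent in WT1 and present in the other strains, and reads of such genes would not follow that ratio, so this value decides nothing on algal reads counted in host genes. A response of the host to the strain and a difference between larval batches, for which the labels give no information, stay open and untested.

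The symbiont genes that set WT1 apart numbered 4.61 times those of the next strain, so the 4 strains were not equally far apart by this count. As the 770 genes are the pattern itself, this describes it and is no separate test. Shared WT1 libraries alone would leave pairs of strains set against different WT1 libraries with about as many common genes as independent lists, but the lowest ratio to these lists over splits and pairs was 8.11, which argues against them as the whole cause. The simulations of unchanged strains gave 0 against 770 genes observed, and as they leave out real differences they decide nothing on the part that shared libraries add. With 1 wild-type strain in the design, a peculiarity of WT1 and an effect of selection cannot be told apart.

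The TMM factors of the host and the symbiont moved together within strains. Across 23 libraries, deviations from the strain means correlated with Pearson r = 0.961 and Spearman rho = 0.900 (permutation p = 1e-05 and 2e-05, the first the smallest that 100000 permutations can give, adjusted p = 3.5e-05 over 7 relations), and r was 0.960 without the 2 farthest libraries. Depth had r = -0.162 with the mean factor and the symbiont share r = -0.0950, both far below 0.961, and r between the organisms stayed at 0.957 without the 50 most abundant genes of each organism and at 0.923 in genes with at least 100 mean counts. An influence on both organisms in a library, such as RNA quality or library preparation, is a candidate explanation that was not tested, and no biological explanation was tested.

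Other splits of the same libraries into groups of the same sizes were counted in fits of 2 groups, with 100 splits per comparison. For the mean comparison these fits pooled the libraries of the heat-selected strains, so its counts here differ from those of the equal-weight comparison. The splits redrew libraries and not strains, so they say nothing on chance among the 4 strains. For the symbiont, 1 split, the real one, gave as many genes in 6 comparisons, which argues against a chance division of the libraries there: the pooled mean comparison gave 2235 genes (highest other 232), SS3 vs WT1 2962 (468), SS5 vs WT1 1753 (767), SS8 vs WT1 1846 (228), SS8 vs SS5 669 (114) and SS5 vs SS3 633 (47). For SS8 vs SS3, 2 of 100 splits gave as many as the real 350. The real split was not the highest, so chance is not excluded there. The other one gave 720 genes and set SS3 replicates 3, 4, 5 and 8 with SS8 replicate 7 against the rest, which points to a structure of the libraries. The mean log2 TMM factor of both organisms differed by 0.07 between its sides, and by -0.02 between the strains. For the host, 1 of 100 splits, the real one, gave as many genes in each comparison, which argues against a chance division of the libraries: 4209 in the pooled mean comparison (highest other 2293), 4549 for SS3 vs WT1 (1225), 4151 for SS5 vs WT1 (644), 5033 for SS8 vs WT1 (191), 5973 for SS8 vs SS3 (405), 1987 for SS8 vs SS5 (1) and 3149 for SS5 vs SS3 (2884). In the last comparison another split came close to the real one. It only exchanged SS5 replicate 6 with SS3 replicate 4 and kept the other libraries with their strains, so it is itself close to the real split. The split with 2293 genes set the SS8 libraries and SS3 replicate 6 against the rest, so it holds a strain difference too.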

How the results depend on the processing

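The exon choice and both covariates were added after the data had been seen. The gene counts without any 1 library (92 recomputed counts per organism, 0 beyond 1.5 times the reported count) and 62 of 76 symbiont and 71 of 83 host counts under other settings stayed within 1.5 times of those reported. Of the values of named genes, 274 of 274 for the symbiont and 298 of 304 for the host kept direction and side of the threshold under other settings, as did 368 of 368 and 367 of 368 without 1 library. No value changed sign past the threshold. The all-3 overlaps were not recomputed without the filter or in fits of 2 strains.

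A minimum of 2-fold left 304, 532, 329, 262, 94, 146 and 146 symbiont genes and 1187, 1010, 1371, 1758, 1415, 483 and 666 host genes, in the order mean, SS3, SS5 and SS8 vs WT1, SS8 vs SS3, SS8 vs SS5 and SS5 vs SS3, since it removes small changes by construction.

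Replicate numbers do not pair the libraries: within-strain deviations of libraries with the same number correlated at a mean r across genes of -0.0299 (symbiont) and -0.0325 (host), and 2 and 3 of 21 libraries were closest to their own number. As a block they left 1567, 157 and 468 symbiont genes for SS3 vs WT1, SS8 vs SS3 and SS5 vs SS3, 2966 and 1666 host genes for SS3 vs WT1 and SS5 vs SS3, and 1272 host genes in the all-3 overlap. Each of these counts involves SS3. Numbers 3 and 4 occur only in SS3, so the block takes SS3 replicates 3 and 4 out of its comparisons. Fewer libraries lower the power, but how far this explains the counts was not tested. Blocked differences of the SS8 share were 11.4 (WT1), 9.90 (SS3) and 13.5 points (SS5), each with an adjusted p of 0.188 in exact sign permutations whose smallest p is 0.0625, 0.125 and 0.0625.

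With the symbiont share as a covariate, 2717, 2426 and 221 host genes differed for SS8 vs WT1, SS3 and SS5, and 1170 lay in the overlap. As SS8 alone has high shares, that covariate and the strain overlap, and a call can end through a smaller fold or a larger SE. For SS8 vs SS5, aten_0.1.m1.34884.m1 kept its log2 fold change (-2.75 ± 0.70 to -2.92 ± 1.48 SE). aten_0.1.m1.9273.m1 lost most of it (3.96 ± 0.67 to 0.43 ± 1.41). Which of these lowered the counts was not tested. With the host's TMM factor as a covariate, 3169, 741, 1527 and 1431 symbiont genes passed for SS5 vs WT1, SS8 vs SS3, SS8 vs SS5 and SS5 vs SS3, and 1268 lay in the overlap. Apart from the 2-fold minimum, the cause of the shifts was not tested.

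Without 1 library, the share difference ranged from -0.812 to 1.06 points for SS3 vs WT1, from -3.20 to -1.33 for SS5 vs WT1 and from -3.07 to -1.78 for SS5 vs SS3. Genes with 0 counts over a strain allow only bounds on their folds.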

Other observations

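The tests of exon usage, of silent genes and of consecutive ID numbers, and the look at SS5 replicate 6, were chosen after the data had been seen. The test on the symbiont share was chosen before its result was seen.

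Counts of exons also shifted within genes (edgeR's test of exon usage, Benjamini-Hochberg adjusted p under 0.05). What shifted them was not tested. The test was not repeated with the block, with the covariates or without single libraries. In the symbiont, SS3 differed from WT1 in exon usage in 906 of 9138 genes, SS5 in 271 and SS8 in 54. SS8 and SS3 differed in 124 genes, SS8 and SS5 in 23 and SS5 and SS3 in 41. In the host, 235, 245 and 264 of 13307 genes differed in the 3 comparisons with WT1, and 230, 73 and 100 among the heat-selected strains in the same order. 33 symbiont and 61 host genes passed in all 3 comparisons with WT1, which share the WT1 libraries. In simulated data for SS8 vs WT1, 97.5% of symbiont genes and 91.5% of host genes with 1 exon changed 4-fold were recovered, and 3.47% and 10.7% of the calls were false. The simulated exons were drawn independently here too.

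Symbiont genes switched fully between strains in few cases. With at most 3 counts over a strain called silent and at least 10 counts in every library called present, 6 genes were silent in WT1 and present in the 3 heat-selected strains, and 5 of these lay on a scaffold with another of the 6. 7 genes were silent in the 3 heat-selected strains and present in WT1, of which 0 lay on a scaffold with another of the 7, and 1 was silent in SS3 and SS5 alone. That 0 depends on the cut. SymbC1.scaffold5068.1.m1 (4, 3 and 5 counts in SS3, SS5 and SS8) narrowly missed it, and SymbC1.scaffold2058.8.m1 (1, 17 and 2) missed it through its counts in SS5. Each lay on a scaffold with 1 of the 7. No host gene met this rule (0 in each pattern). The rule is in counts, and host libraries are deeper, so silence was defined more strictly for the host. 3 counts over WT1 equal 0.0238 CPM in the host and 0.102 CPM in the symbiont. aten_0.1.m1.6676.m1, with 9 counts over the WT1 libraries (0.0779 CPM), was thus not called silent. The numbers of the 2 organisms are therefore not comparable.

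Neighbouring genes may switch together. Among 7626 pairs of symbiont genes with consecutive numbers on a scaffold, 264 pairs passed in the same direction in the mean comparison, against 97.6 in 1000 shuffles of the calls (highest 126, permutation p = 0.001, the smallest they can give), while 49 passed in opposite directions against 90.8 in the shuffles. Among 13022 host pairs, 996 passed in the same direction against 584 (highest 664, permutation p = 0.001), and 531 in opposite directions against 581. The excess, 2.70- and 1.71-fold, was 2.498- and 1.56-fold for pairs with 1 number between. Copies that share reads, shared regulation and, for the symbiont, missing stretches of sequence were not told apart by this test, and host ID numbers are only assumed to follow position.

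Whether the host genes at least 4-fold higher follow the symbiont share was tested within strains. Their mean log2 CPM and the logit of the share had r = -0.0816 and rho = -0.0781 over 23 libraries (permutation p = 0.688 and 0.715, adjusted p = 0.688 over 7 relations), and r = -0.0959 without the 2 farthest libraries. No relation was detectable with these libraries.

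SS5 replicate 6 had a host profile apart from its strain, at -6.97 on the first host component against 15.2 to 44.4 in the other SS5 libraries, and on the first symbiont component it lay at -28.0, lowest of the SS5 libraries. Its symbiont carried SymbC1.scaffold745.5.m1 at 26.5 CPM, a gene with 0 counts in SS3, 2 in SS8 and 14 in WT1. The naming rule picked this gene because every SS5 library lay above those of SS3 and SS8. Its presence in replicate 6 was thus set by the choice and is no check on the strain of this library. Without this library 4190 host genes differed between SS5 and SS3, against 3162 with it, and 5237 between SS5 and WT1, against 5041. The labels do not say whether its larvae, its algae or its RNA could have been mixed up or come from another batch. This was not tested, and the SS5 values of both organisms include this library. The split of these libraries with 2884 genes exchanged it with SS3 replicate 4.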
